A study of Homo sapiens with 12 samples.

How the data were processed

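Total RNA from HK-2 cells, prepared with a silica column kit, was labelled as biotinylated cRNA and hybridised to Affymetrix arrays with 54675 probe sets, 1 array per culture. The 12 arrays form 4 groups of 3 (control 24 h, Nnm 24 h, control 48 h and Nnm 48 h), labelled as biological replicates, and the vehicle control of the same time is the baseline for each Nnm group. The number of arrays limits the precision.

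The deposited values are log2 expression values that the authors made with GCRMA, a method that subtracts background by probe sequence, normalises across arrays by quantiles and summarises each probe set, per the submitters' processing notes. The version is not given in the sources used here, and neither is the set of arrays that were normalised together. The log base was inferred from the range of the values.

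Probe sets were named from the annotation table of the platform. Of the 54675 probe sets, 62 were controls, 41097 had 1 gene symbol, 1801 had several and 11777 were not listed there. Gene IDs of 41043 probe sets were found in the RefSeq table of assembly GRCh38.p14, which served for names alone and changed 0 symbols. Probe sets above a log2 of 4 on at least 3 arrays were kept (19832 with 1 gene). Each gene was taken from its probe set with the highest mean over all arrays, which gave 10907 genes, 5320 of them with more than 1 kept probe set. Probe sets with no gene or several genes were tested apart and appear in the closing section alone.

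Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes over all 12 arrays), with p adjusted by the method of Benjamini and Hochberg over all genes tested and a threshold of 0.05. The comparisons were Nnm against control at 24 h and at 48 h, the mean of these changes, their difference, and control 48 h against control 24 h. Every SE is limma's, from a spread pooled over the 12 arrays. The gene lists, 34 in number with 699 genes in all, were written from textbook knowledge before the data were examined, as were the named-gene rule, the comparisons and all but one of the alternatives. The 32 lists with at least 5 tested genes were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists. Beside it stand camera with the correlation estimated from the residuals, under which no list was called in any comparison, and fry, which tests whether a list's genes move one way on balance and does not compare them with other genes.

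The genes named are the 10 largest rises and 10 largest falls past the threshold at each time whose 3 Nnm values lay outside the 3 control values, and up to 4 members of each list with the smallest p. Also named are the 5 rises and 5 falls with the smallest p for the mean of both times, the 2 smallest p in each direction for the difference between times, where none passed, and all genes that passed between the control groups. A gene outside this rule is marked as chosen after its values were seen. Of the 183 genes named, 89 have more than 1 kept probe set. All probe sets of a gene had the same direction in 80 of these at 24 h and 78 at 48 h. The exceptions were ABCC3, ACLY, CDH6, NRG1, PSPH, SLC11A2, SLC35F5, TNFRSF10A and TOP2A at 24 h, and ABCC3, CDH6, CLCN4, MT1E, NRG1, OCLN, PPM1D, SCNN1A, SLC11A2, SLC30A1 and SLC35F5 at 48 h.

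Whether the replicate numbers pair the arrays was checked on the residuals after the group means were removed. Arrays of the same number and time correlated at 0.34 to 0.512 and of the same number in any groups at 0.318 to 0.696, against -0.587 to 0.119 for different numbers, so the numbers pair the arrays across groups. The planned test has no block, and the value with the replicate number as a block stands beside a result printed in the text where the call changes or a total count moves more than 1.5 times. The 48 further results of named genes that pass with the block alone are given as a number, apart from NOCT.

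The tests were tried on simulated data of the same size and spread, with noise drawn independently for each gene and array and few genes changed. The pairing of the arrays and the correlation between genes were not simulated, so recovery and false calls in the real data can differ. Changes of 0.5, 1 and 2 log2 units were recovered in 17.9%, 74.6% and 95.5% of genes for the 24 h comparison. The shares were 26.9%, 58.2% and 97% for 48 h and 23.9%, 73.1% and 92.4% for the control groups. Beside them 5, 8 and 6 unchanged genes were called, and in data with no change at all 0 genes were. Alternatives tried were no filter and a stricter filter (a log2 of 6), the mean of a gene's probe sets, quantile normalisation and median centring of the arrays. Others were array weights, trend and robust settings, the replicate block over all arrays and within each time, the groups compared alone, each array left out in turn, and both Nnm replicate 2 arrays left out. The plots were drawn with Python 3.11.15 and matplotlib 3.10.9. GC content was not analysed here, and no genome positions are given.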

Results

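Gene expression was measured in HK-2 cells, an immortalised line of human kidney proximal tubule epithelium, that had been kept for 24 h or 48 h with a low dose of the compound labelled Nnm or with vehicle alone. The series is part of a survey of compounds for expression changes linked to kidney toxicity. Each of the 4 groups (control 24 h, Nnm 24 h, control 48 h and Nnm 48 h) held 3 arrays from separate biological replicates, 12 arrays in all, and that number limits the precision. Each array gave a log2 expression value for 54675 probe sets, of which 40.4% to 40.8% lay above 4, and 10907 genes were bright enough to test.

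The 6 control arrays lay at 18.6 to 34.4 on the first principal component, which held 50.3% of the variance, and the Nnm arrays of replicates 1 and 3 lay at -31.2 to -43.2. The Nnm arrays of replicate 2 lay between these at both times (-1.55 at 24 h and -3.28 at 48 h). Across genes, the change of each Nnm array from the control array of its number was set against the change of another replicate at the other time, so that no reference held the number tested. Against replicate 1, the slope of replicate 2 was 0.361 (24 h) and 0.244 (48 h), and that of replicate 3 was 0.749 and 0.636. Against replicate 3, the slope of replicate 2 was 0.413 and 0.266, and that of replicate 1 was 0.819 and 0.674. The log2 difference between the 5′ and 3′ probe sets of ACTB (beta-actin), a sign of RNA quality, was -1.09 to -1.17 on the replicate 2 arrays of all 4 groups. On the other arrays it was -0.74 to -0.86. The same difference for GAPDH, a second control gene, did not set replicate 2 apart. It was 0.0624 to 0.158 on the replicate 2 arrays and 0.0293 to 0.162 on the others.

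After 24 h with Nnm, the largest rise was that of SLC16A14, a member of the monocarboxylate transporter family, which went from 2.73 ± 0.44 to 8.43 ± 1.11 (mean log2 value ± SD, n = 3). TXNIP, an inhibitor of thioredoxin that responds to glucose, rose from 9.45 ± 0.36 to 12.11 ± 0.25, and NRG1, a growth factor of the EGF family, fell from 9.19 ± 0.36 to 6.03 ± 1.75. The comparison asks which genes respond to Nnm within a day. Of the 10907 genes, 2116 changed (1151 rose and 965 fell) at an adjusted p under 0.05 (limma), and 336 of the rises and 221 of the falls were larger than 2-fold. The 3 Nnm values did not overlap the 3 control values in 39.8% of all genes, where chance gives 10%, and with the replicate number as a block the count was 4237. With arrays centred on their medians 1074 rose and 1008 fell.

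The rises over 2.5 log2 units belonged to genes of several kinds. SLC16A14 rose by 5.70 (SE 0.60, adjusted p = 0.00307), and its relative SLC16A9 by 4.51 (SE 1.05). PCLO, a presynaptic scaffold protein, rose by 4.12 (SE 0.63), and C5AR1, the receptor of complement fragment C5a, by 3.69 (SE 0.64, adjusted p = 0.00752). The histone demethylase KDM7A rose by 3.19, the protease CAPN5 by 2.81, the growth arrest protein GAS1 by 2.81, the adhesion protein TENM3 by 2.79, the signalling protein THEMIS2 by 2.66 and TXNIP by 2.66 (SE 0.59, adjusted p = 0.016). Among the falls were NRG1 at -3.16 (SE 0.76, adjusted p = 0.0203), though at -0.92 with the mean of its probe sets, which did not all move the same way, and the non-coding RNAs LINC01111 at -2.75, ZFHX4-AS1 at -2.65 (-1.67 with the mean of its probe sets) and LOC101928409 at -2.36. The pseudogene ZBED10P (-2.61), the synapse protein CBLN2 (-2.61), the tight junction protein CLDN2 of the proximal tubule (-2.59), the membrane protein TM4SF4 (-2.49), the AP-1 subunit FOSL1 (-2.49) and C1orf116 (-2.36) also fell, with adjusted p from 0.00721 to 0.0462. The control means of SLC16A14, SLC16A9, C5AR1, KDM7A and GAS1, and the Nnm means of LINC01111, LOC101928409, CBLN2 and FOSL1, were under a log2 of 4, close to background, so the size and rank of these changes depend on how background was subtracted.

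Without any 1 array, SLC16A14, PCLO, C5AR1, TENM3, ZBED10P, CBLN2, TM4SF4, C1orf116 and LOC101928409 kept their calls (9 of these 20 genes). The other 11 lost theirs without Nnm replicate 1 or 3 or a control array of 24 h, with adjusted p of up to 0.119 (CAPN5). CLDN2 also lost it without 5 of the 48 h arrays, at up to 0.163. The count of changed genes was 616 without Nnm 24 h replicate 1, 537 without Nnm replicate 3, 931 without control replicate 1 and 404 without control replicate 3. It was 3248 without Nnm 24 h replicate 2.

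At 24 h, in the list of NRF2 targets and glutathione genes, 7 of 20 rose, 0 fell and 13 did not pass (8 rose adjusted over the list alone). TXNRD1 (thioredoxin reductase) rose by 1.71 (SE 0.31), NQO1 (a quinone reductase) by 1.36 (SE 0.23) and SLC7A11 (the cystine importer) by 2.25 (SE 0.55). The list as a set was higher, at a median of 0.64 (camera adjusted p = 0.00135, and adjusted p = 0.633 with an estimated correlation). Without the Nnm replicate 2 arrays 11 of the 20 rose. Those Nnm arrays changed least, so higher counts without them, here and below, follow in part from that choice and are no separate support. Of 10 glucocorticoid targets, 5 rose and 5 did not pass (5 rose adjusted over the list alone), among them the transcription regulator TSC22D3 by 1.70 (SE 0.41), the phosphatase DUSP1 by 1.05 and PCK1, an enzyme that makes glucose, by 0.81. That list had a median of 0.56 (camera adjusted p = 0.016, and adjusted p = 0.45 with an estimated correlation) and was not called without Nnm 24 h replicate 2 (adjusted p = 0.0593). Metallothioneins and their zinc exporter had a median of 0.32 (camera adjusted p = 0.0465, and adjusted p = 0.822 with an estimated correlation), with 1 of 8 past the threshold (MT1E, 0.40, 0 adjusted over the list alone). With the replicate number as a block that list had an adjusted p of 0.0903. Without Nnm 24 h replicate 1 or 3, Nnm 48 h replicate 2, control 24 h replicate 2 or control 48 h replicate 3 it was also not called (adjusted p up to 0.0983).

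In the ribosome biogenesis list 10 of 17 genes fell at 24 h, 0 rose and 7 did not pass (14 fell adjusted over the list alone). The median was -0.55 (camera adjusted p = 1.5e-06, and adjusted p = 0.633 with an estimated correlation). POLR1A, the large subunit of RNA polymerase I, fell by 1.25 (SE 0.21), the small subunit assembly factor UTP4 by 0.95 (SE 0.20) and the helicase DDX21 by 0.81 (SE 0.13). In oxidative phosphorylation 6 of 21 fell, 0 rose and 15 did not pass (10 fell adjusted over the list alone), at a median of -0.31 (camera adjusted p = 6.74e-05, and adjusted p = 0.633 with an estimated correlation). The complex I subunit NDUFS1 fell by 0.82, cytochrome c (CYCS) by 0.78 (-1.18 with the mean of its probe sets) and the ATP synthase subunit ATP5F1B by 0.60 (SE 0.12). In cholesterol synthesis 4 of 19 fell, 0 rose and 15 did not pass (9 fell and 1 rose adjusted over the list alone), among them ACAT2 by 1.53 and NSDHL by 1.13. The median was -0.43 (camera adjusted p = 0.00264, and adjusted p = 0.633 with an estimated correlation). Without the Nnm replicate 2 arrays 12 ribosome biogenesis, 11 oxidative phosphorylation and 9 cholesterol synthesis genes fell.

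Camera called these 6 of 32 lists at 24 h, and 11 without Nnm 24 h replicate 2. Of the 10 splits of the 24 h arrays into 3 and 3, 5 gave at least 6 lists, the real one included, and the highest other gave 13. The number of lists called at 24 h therefore does not stand apart from other groupings of the arrays. Fry, which asks whether a list's genes move one way on balance, called 8. It left out metallothioneins (fry adjusted p = 0.0986) and also called fatty acid synthesis (0.0175), iron handling (0.0375) and distal nephron markers (0.00188). Without both Nnm replicate 2 arrays, an alternative chosen after the data were seen, 5 further lists were called at 24 h. These were ATF4 targets (10 rose and 1 fell of 24, camera adjusted p = 0.0293), lysosome genes (6 rose of 22, 0.0293), the cell cycle (4 fell of 25, 0.0351), DNA replication (2 rose and 6 fell of 23, 0.0362) and histone genes (2 fell of 7, 0.0362), with adjusted p = 0.372 to 0.857 with an estimated correlation. Several lists outside the 6 also held changed genes with all arrays. Over all genes 19.4% were called at 24 h, so a 24 h count near or under that share does not set a list apart. Among 9 iron handling genes, 2 rose and 1 fell (3 rose and 1 fell adjusted over the list alone), led by the iron exporter SLC40A1 at 1.64 (SE 0.24). Of 17 TGF-beta targets, 3 fell (3 fell adjusted over the list alone). The activin subunit INHBA fell by 2.05 (SE 0.21, adjusted p = 0.00299), the matrix protein THBS1 by 1.91 (-3.28 with the mean of its probe sets) and the clock regulator BHLHE40 by 0.81. Of 18 NF-kB and cytokine genes, the inhibitor NFKBIA rose by 0.61 while IL32 fell by 1.51, ICAM1 by 0.97 and CXCL8 by 0.91 (the same 1 and 3 counts adjusted over the list alone). Of 21 apoptosis genes, 3 rose, such as the death ligand TNFSF10 by 0.75, and 2 fell, such as BAX by 0.41 (3 and 3 adjusted over the list alone). Of 23 hypoxia and glycolysis genes, 2 rose and 3 fell (2 and 3 adjusted over the list alone), among the falls PDK1 by 0.93 and PGK1 by 0.59 (-1.0 with the mean of its probe sets). Of 17 interferon genes 3 rose (5 adjusted over the list alone), such as OAS1 by 1.33, and of 22 lysosome genes 3 rose (2 adjusted over the list alone), such as GABARAPL1 by 0.81. Of 23 immediate early genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone), and of 9 xenobiotic metabolism genes 2 rose (2 adjusted over the list alone), CYP1B1 by 1.05 and NQO1.

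The p53, DNA repair and kidney injury lists were not called as sets at 24 h either. Of 24 p53 targets 1 rose and 4 fell (1 and 5 adjusted over the list alone), among them the phosphatase gene PPM1D, which rose by 0.54, and the kinase gene PLK2, which fell by 1.77. Of 19 DNA repair genes 2 fell (1 adjusted over the list alone), LIG1 by 0.98 and PARP1 by 0.40. Of 20 kidney injury markers 1 rose and 1 fell (1 rose adjusted over the list alone), the rise being CLU (clusterin) at 0.76. In the cell cycle list 2 of 25 fell, in DNA replication 1 rose and 2 fell of 23 and in histone genes 1 of 7 fell (0, 0 and 1 adjusted over the list alone). In the unfolded protein response 2 rose and 3 fell of 18 (2 and 6 adjusted over the list alone). In the ATF4 list 1 rose and 1 fell of 24, and in fatty acid synthesis 1 rose and 2 fell of 10 (as many adjusted over the list alone). In PPAR and fatty acid oxidation 1 of 12 rose, PDK4 by 1.18 (1 adjusted over the list alone). One heat shock gene of 11, HSPE1, fell by 0.50 (SE 0.15), with 0 adjusted over the list alone, and 0 of 16 ribosomal proteins passed.

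Of the markers of kidney segments and other cell types, 4 rose and 0 fell at 24 h. The collecting duct transcription factor TFCP2L1 rose by 1.67 (SE 0.21, adjusted p = 0.00496, or by 1.07 with the mean of its probe sets) and the sodium channel subunit SCNN1A by 0.75, 2 of the 5 distal nephron markers tested (3 rose and 1 fell adjusted over the list alone). One proximal tubule marker of 5, the peptidase DPP4, rose by 0.77 (2 rose and 1 fell adjusted over the list alone), and one podocyte marker of 5, SYNPO, by 0.79 (2 adjusted over the list alone, and adjusted p = 0.0508 with a replicate block within each time). In the epithelial junction list OCLN rose by 0.78 (0.33 with the mean of its probe sets, which did not pass, adjusted p = 0.159) and 2 of 17 fell, one of them cingulin (CGN), from 7.16 ± 0.05 to 5.66 ± 0.49 (1 and 2 adjusted over the list alone). None of 12 fibroblast, 4 endothelial and 1 leukocyte marker tested changed (0 adjusted over the list alone), though 2 fibroblast markers rose without both Nnm replicate 2 arrays. Of the list members named for 24 h 68 were past the threshold, and 14 of them stayed past it without each array in turn. With the mean of their probe sets CAPN5, PPM1D, ICAM1, PDK1 and NDUFS1 did not pass at 24 h, at adjusted p of 0.0512 to 0.0973. Nor did LSS (0.155), CDT1 (0.162), TNFRSF10A (0.117), SLC11A2 (0.261) and WDR12 (0.122), which are among the genes counted in the lists above.

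After 48 h with Nnm, SLC16A14 and TXNIP had the largest rises, at 6.22 and 6.13 too close to rank. TXNIP rose from 6.03 ± 1.56 to 12.16 ± 0.40 (mean log2 value ± SD, n = 3). KRT20, a keratin of differentiated epithelium, fell from 8.92 ± 0.59 to 5.32 ± 0.91, and the secreted glycoprotein CHI3L1 from 9.05 ± 0.28 to 6.90 ± 0.26. The comparison asks which responses are present after 2 days. Of 10907 genes, 1504 changed (limma), 922 up and 582 down, with 260 rises and 127 falls over 2-fold. The 3 Nnm and 3 control values did not overlap in 36.1% of genes, where chance gives 10%, and the replicate block gave 3515 genes. With arrays centred on their medians 797 rose and 705 fell.

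SLC16A14 rose by 6.22 (SE 0.60), TXNIP by 6.13 (SE 0.59, adjusted p = 0.0012) and SLC16A9 by 4.19 (SE 1.05, adjusted p = 0.0284). The short-chain dehydrogenase DHRS2 rose by 5.17 (SE 1.35, adjusted p = 0.0317). SHISA2, an inhibitor of Wnt and FGF receptor maturation, rose by 3.07 and RSPO3, which enhances Wnt signalling, by 3.07. The adhesion protein NEGR1 (2.98), the choline transporter SLC44A2 (2.87), C5AR1 (2.84) and PCLO (2.74) followed. KRT20 fell by 3.60 (SE 0.65, adjusted p = 0.0107), the non-coding RNA UCA1 by 3.22 (SE 0.60) and CHI3L1 by 2.15 (SE 0.22, adjusted p = 0.0012). The glycolysis regulator PFKFB2 (-2.19), the reductase DHRS11 (-2.19), the basement membrane collagen COL4A3 (-2.16), the cyclin CCND2 (-2.10), CCDC146 (-2.70), LINC01111 (-2.54) and ZBED10P (-2.45) fell with adjusted p from 0.00605 to 0.0456. The control means of SLC16A14, SLC16A9, DHRS2, SHISA2 and NEGR1, and the Nnm means of UCA1, CCDC146, LINC01111 and COL4A3, were under a log2 of 4, close to background.

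Without any 1 array, SLC16A14, TXNIP, SHISA2, KRT20, DHRS11 and CHI3L1 kept their calls (6 of these 20 genes). The other 14 lost theirs without Nnm replicate 1 or 3 or a control array of 48 h, with adjusted p of up to 0.122 (DHRS2). CCDC146 also lost it without 4 of the 24 h arrays, at up to 0.165. The count of changed genes was 267 without Nnm 48 h replicate 1, 381 without Nnm replicate 3, and 387, 888 and 419 without control 48 h replicates 1, 2 and 3. It was 2403 without Nnm 48 h replicate 2.

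In oxidative phosphorylation 11 of 21 fell at 48 h, 0 rose and 10 did not pass (17 fell adjusted over the list alone), at a median of -0.42 (camera adjusted p = 5.81e-09, and adjusted p = 0.312 with an estimated correlation). NDUFS1 fell by 0.94 (SE 0.19), ATP5F1B by 0.92 (SE 0.12), UQCRC1 of complex III by 0.66 and CYCS by 0.61 (-0.93 with the mean of its probe sets). In cholesterol synthesis 6 of 19 fell, 0 rose and 13 did not pass (9 fell adjusted over the list alone), at a median of -0.56 (camera adjusted p = 6.07e-06, and adjusted p = 0.336 with an estimated correlation). ACAT2 fell by 1.28, NSDHL by 0.80, lanosterol synthase (LSS) by 0.78 and the sterol carrier STARD4 by 0.77. In fatty acid synthesis 5 of 10 fell and 5 did not pass (6 fell adjusted over the list alone), at a median of -0.44 (camera adjusted p = 0.00156, and adjusted p = 0.265 with an estimated correlation). The lipase gene PNPLA3 went from 8.02 ± 0.14 to 6.52 ± 0.52 (mean ± SD, n = 3), and fatty acid synthase (FASN) fell by 1.22 (SE 0.22), ACSS2 by 0.99 and ACLY by 0.55. The PPAR and fatty acid oxidation list had an adjusted p of 0.0562 and passed with the replicate block (adjusted p = 0.0487) and without both Nnm replicate 2 arrays (adjusted p = 0.0331, and adjusted p = 0.244 with an estimated correlation). In it 1 of 12 rose, PDK4 by 1.00, and 3 fell, ETFDH by 0.73, ACADM by 0.57 and HADHA by 0.43 (1 and 4 adjusted over the list alone). Without the Nnm replicate 2 arrays 17 oxidative phosphorylation, 10 cholesterol synthesis and 6 fatty acid synthesis genes fell.

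In the unfolded protein response list 4 of 18 fell at 48 h, 0 rose and 14 did not pass (9 fell adjusted over the list alone), at a median of -0.33 (camera adjusted p = 0.00163, and adjusted p = 0.413 with an estimated correlation). The chaperone cofactor SDF2L1 fell by 1.16 (SE 0.31, but -0.76 at an adjusted p of 0.103 without Nnm 48 h replicate 1) and CRELD2 by 0.86. In ribosome biogenesis 3 of 17 fell, 0 rose and 14 did not pass (5 fell adjusted over the list alone), at a median of -0.42 (camera adjusted p = 0.000387, and adjusted p = 0.486 with an estimated correlation): UTP4 by 0.79, WDR12 by 0.65 and DDX21 by 0.59. One histone gene of 7, H2BC12, fell by 1.34 (1 adjusted over the list alone) in a list with a median of -0.78 (camera adjusted p = 0.00896, and adjusted p = 0.413 with an estimated correlation). Without a filter on low values that list lay at -0.23 and was not called (adjusted p = 0.144). It lay at -0.51 under the stricter filter and at -0.39 without Nnm 48 h replicate 3, and kept its call in both.

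In the cell cycle and mitosis list 7 of 25 were higher than in control cells of 48 h, 0 were lower and 18 did not pass (9 adjusted over the list alone, and 4 higher over all genes with arrays centred on their medians). The median was 0.46 (camera adjusted p = 1.96e-05, and adjusted p = 0.633 with an estimated correlation), or 0.27 without Nnm 48 h replicate 3. CCNA2 (cyclin A2) was higher by 0.91 (SE 0.22), TOP2A (topoisomerase IIα) by 0.80 (SE 0.15, though by 0.63 and at an adjusted p of 0.052 with the mean of its probe sets) and the spindle motor KIF11 by 0.66, and without the Nnm replicate 2 arrays 13 were higher. In DNA replication 2 of 23 were higher (0 adjusted over the list alone), the replication factor MCM10 by 1.11 and ORC1 by 1.08. That list had a median of 0.25 (camera adjusted p = 0.0482, and adjusted p = 0.914 with an estimated correlation), or 0.39 without control 48 h replicate 3. It was not called without Nnm 24 h replicate 3, Nnm 48 h replicate 3, control 24 h replicates 2 or 3, or control 48 h replicates 1 or 2, with adjusted p up to 0.207. Of 17 interferon genes, IFIT2 rose by 1.40 and IFIT1 by 1.22 and 15 did not pass (7 rose adjusted over the list alone), at a median of 0.60 (camera adjusted p = 0.00249, and adjusted p = 0.336 with an estimated correlation). Of 10 glucocorticoid targets 3 rose and 7 did not pass (3 adjusted over the list alone), PCK1 by 2.11 (SE 0.21, adjusted p = 0.0012), NFKBIA by 0.89 and DUSP1 by 0.89. The median was 0.43 (camera adjusted p = 0.0125, and adjusted p = 0.265 with an estimated correlation), and 0.67 without both Nnm replicate 2 arrays. With arrays centred on their medians an 11th gene passed the filter, and the median of the 11 was 0.25.

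Over all genes 13.8% were called at 48 h, so a 48 h count near or under that share does not set a list apart. Antioxidant genes were not called as a set at 48 h (camera adjusted p = 0.102). Without both Nnm replicate 2 arrays they were, at a median of 0.37 with 5 of 20 higher and 1 lower (camera adjusted p = 0.0118, and adjusted p = 0.155 with an estimated correlation). With all arrays 3 of 20 rose (4 adjusted over the list alone): TXNRD1 by 1.21, NQO1 by 1.01 and the exporter ABCC3 by 1.00, whose probe sets did not all move the same way (adjusted p = 0.0903 with their mean). In the xenobiotic metabolism list 3 of 9 rose, CYP1B1 by 1.31 (SE 0.20) and CYP2J2 by 1.06 besides NQO1, and TIPARP fell by 1.24 (3 and 2 adjusted over the list alone). Of 20 kidney injury markers 3 rose (4 adjusted over the list alone), the adhesion molecule VCAM1 by 1.43, the cytokine IL18 by 0.78 and TIMP1 by 0.45. Of 23 hypoxia and glycolysis genes 4 fell (4 adjusted over the list alone), among them PDK1 by 1.38 and PFKP by 0.70. Of 24 ATF4 targets 3 fell (3 adjusted over the list alone), including VLDLR by 1.02 and the tRNA synthetase WARS1 by 0.92. TIGAR fell by 0.81, and 3 of 24 p53 targets fell and 1 rose (3 and 1 adjusted over the list alone). BLM rose by 0.85, alone of 19 DNA repair genes (0 adjusted over the list alone), and TNFSF10 by 0.98 among 2 of 21 apoptosis genes (2 adjusted over the list alone).

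Segment and cell type markers moved both ways at 48 h. DPP4 rose by 1.19 and the creatine pathway enzyme GATM fell by 0.59, of 5 proximal tubule markers (1 and 1 adjusted over the list alone, and for GATM adjusted p = 0.0529 with a replicate block within each time). SCNN1A rose by 0.71, alone of 5 distal nephron markers (1 adjusted over the list alone). Cadherin 6 (CDH6) rose by 1.38 while CGN fell by 1.37 and CRB3 by 0.68 in the list of 17 junction genes (1 and 2 adjusted over the list alone). The probe sets of SCNN1A and CDH6 did not all move the same way, and with their mean neither passed (adjusted p = 0.193 and 0.235). Of 12 fibroblast markers S100A4 fell by 0.89 and COL1A1 by 0.53 (2 fell and 3 rose adjusted over the list alone). Of 17 TGF-beta targets 2 fell (2 adjusted over the list alone), COL4A1 by 0.75 and BHLHE40 by 0.64. One NF-kB gene of 18 rose (NFKBIA) and one fell, ICAM1 by 1.00 (1 and 1 adjusted over the list alone). One immediate early gene of 23 rose (DUSP1) and one fell, MYC by 0.66 (6 and 1 adjusted over the list alone). Without both Nnm replicate 2 arrays 11 rose and 1 fell, and the list was called at a median of 0.65 in place of 0.28 (camera adjusted p = 0.00293, and adjusted p = 0.283 with an estimated correlation). One of 22 lysosome genes, CTSL, rose by 0.85 (0 adjusted over the list alone) and one of 9 iron handling genes, SLC40A1, by 1.39 (1 adjusted over the list alone). None of the metallothionein, heat shock, ribosomal protein, podocyte, endothelial or leukocyte marker lists held a changed gene (1 endothelial marker rose adjusted over the list alone). Without both Nnm replicate 2 arrays 2 heat shock genes, 1 podocyte marker and 1 leukocyte marker rose. Camera called 10 of 32 lists at 48 h, and 2 of the 10 splits of these arrays into 3 and 3 reached 10 lists, the real one included. Fry called 9, leaving out the cell cycle (fry adjusted p = 0.0671) and DNA replication (0.182) and adding PPAR and fatty acid oxidation (0.00259). Of the list members named for 48 h 67 were past the threshold, and 15 of them stayed past it without each array in turn. With the mean of their probe sets NEGR1, NSDHL, MCM10, ICAM1, NDUFS1, GATM, COL1A1, BHLHE40, DUSP1 and WDR12 did not pass at 48 h either, at adjusted p of 0.0518 to 0.135.

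**Figure D1:**
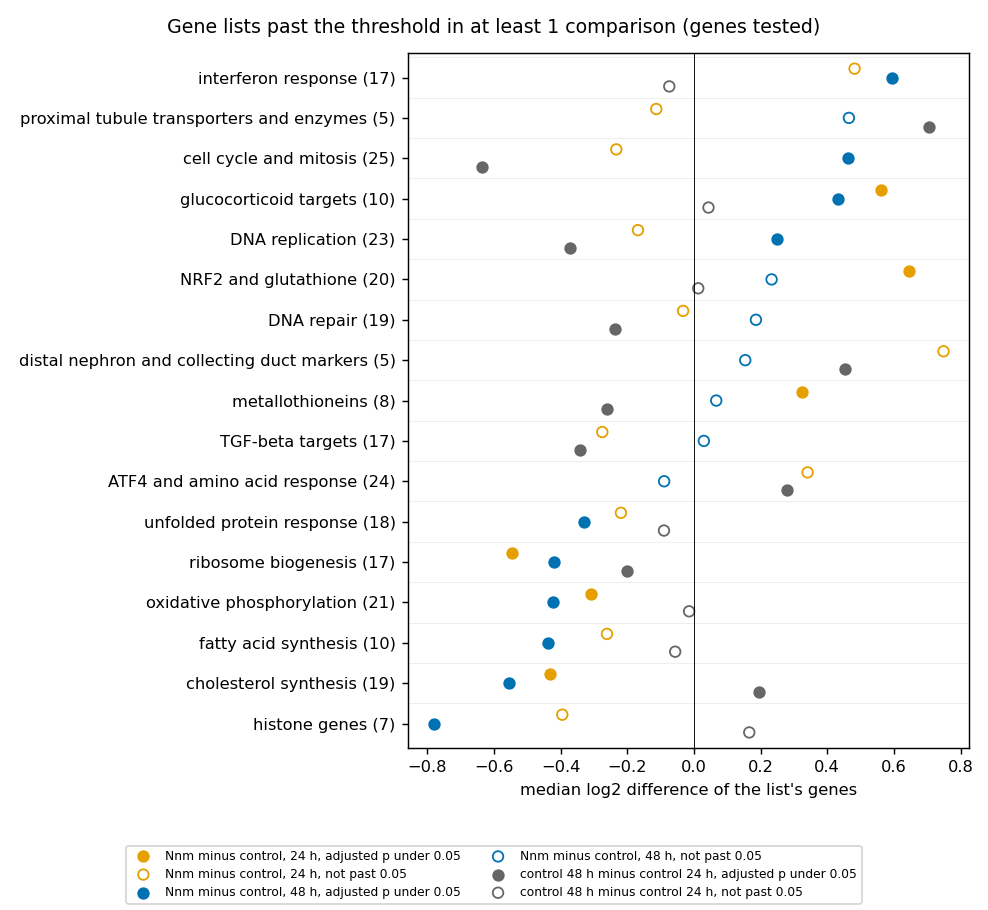
For each gene list, the median log2 change of Nnm against control at 24 h and 48 h and of control 48 h against control 24 h is on the horizontal axis, and filled symbols mark lists that camera called at an adjusted p under 0.05 with its preset correlation. Ribosome biogenesis (-0.55 and -0.42) and cholesterol synthesis (-0.43 and -0.56) were lower at both times, and the cell cycle list lay at 0.46 for Nnm at 48 h and at -0.64 for control 48 h against control 24 h.

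**Figure D2:**
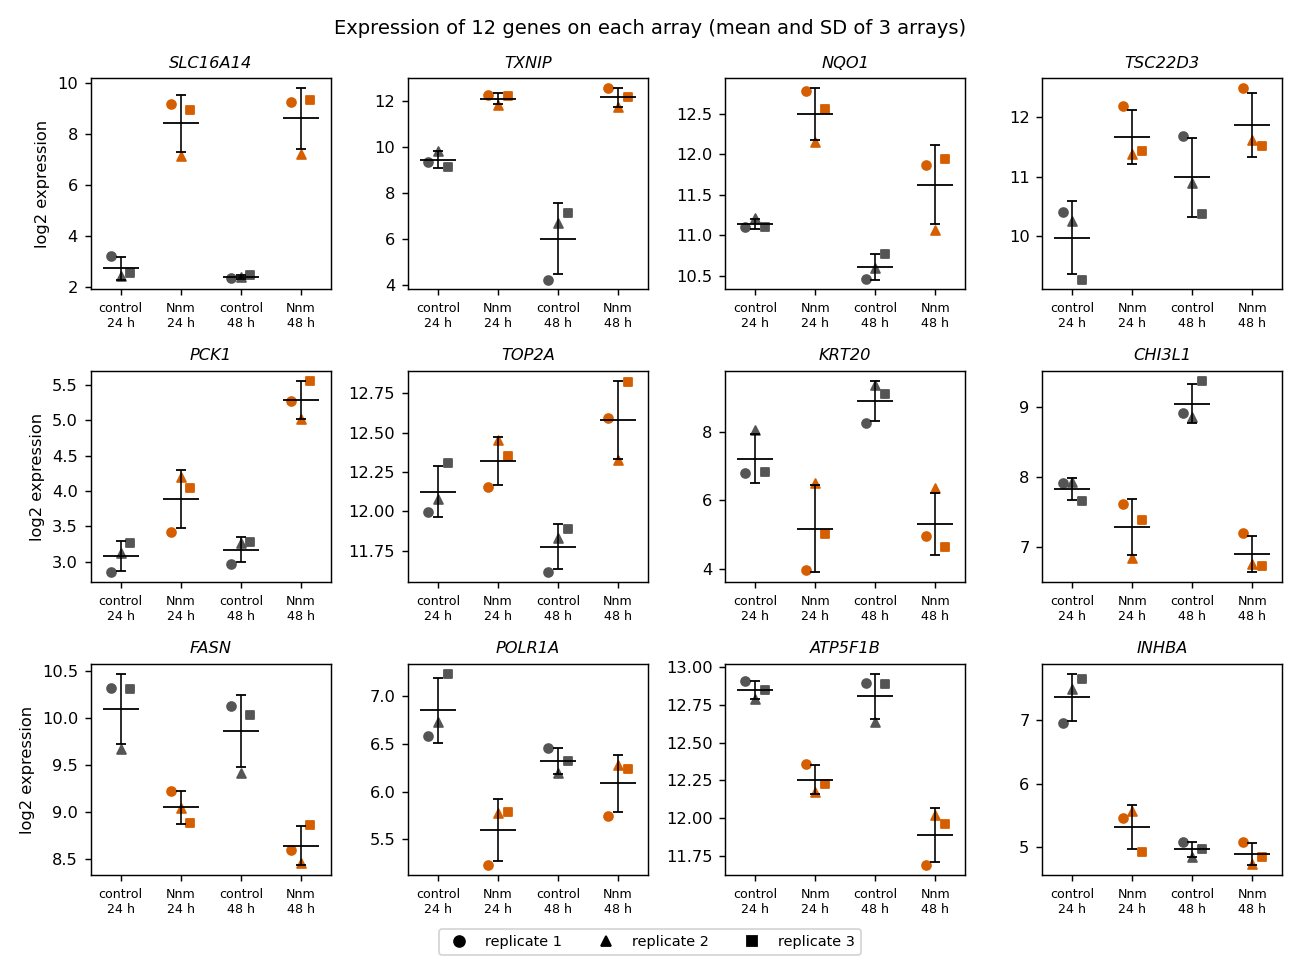
Log2 expression of 12 genes named in the text is shown for each array, with markers for the replicate and bars for the group mean ± SD (n = 3). In SLC16A14 and TXNIP all Nnm values lie above the control values of the same time, and TXNIP has control means of 9.45 at 24 h and 6.03 at 48 h.

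Across genes, the changes at 24 h and 48 h were alike. The 521 genes that rose and 328 that fell at both times, such as SLC16A14, NQO1, PCK1 and SLC40A1 among the rises and CGN, ATP5F1B, NSDHL and WARS1 among the falls, compare with 97.3 and 51.5 if the 2 calls were independent. Of 2770 genes called at either time, 2641 (95.3%) had the same sign at both. One gene, the chloride transporter CLCN4, was called in opposite directions, with a rise of 0.80 at 24 h (adjusted p = 0.00898) and a fall of 0.57 at 48 h (adjusted p = 0.0321). It was picked out here after its values were seen, and its probe sets did not all move the same way at 48 h. The changes correlated across the 10907 genes at r = 0.788 (Spearman rho = 0.752), and with the changes taken within replicate 1, 2 or 3 alone r was 0.71, 0.644 and 0.717. Genes are not independent replicates, so no p is given for r. Arrays of the same number had correlated residuals across the times, and replicate 2 changed less at both. The times are thus not independent repeats, and the shared replicates can raise the overlap and r.

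**Figure D3:**
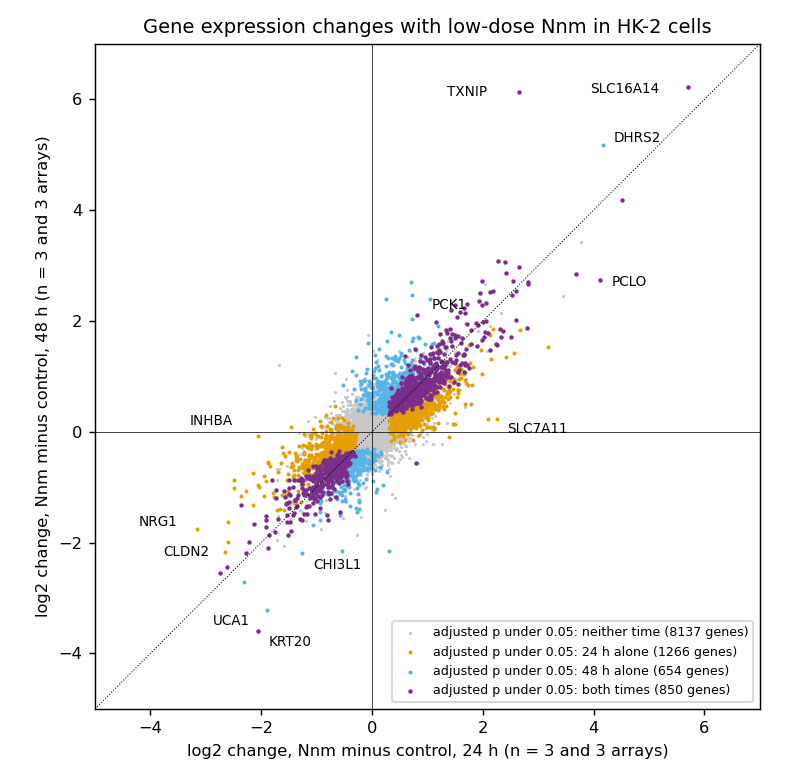
Each point is one of the 10907 genes, with its log2 change with Nnm at 24 h on the horizontal axis and at 48 h on the vertical axis, and colour for the time at which it was called. The 850 genes called at both times lie along the diagonal, 521 of them up and 328 down at both and CLCN4 opposite, and r across genes is 0.788.

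The mean change of both times asks which genes responded to Nnm at 24 h and 48 h taken as one. It was past the threshold in 4067 genes (2229 up and 1838 down; limma), or 2017 up and 2016 down with arrays centred on their medians. The smallest adjusted p belonged to the non-coding RNA NR2F1-AS1, which rose by 1.81 (SE 0.12, adjusted p = 0.000156), SLC16A14, which rose by 5.96, and the arrestin family gene ARRDC3, a relative of TXNIP, which rose by 1.92 (SE 0.14). The chemokine CCL28 rose by 1.66 and ELMOD1 by 1.87. The nuclear import receptor IPO4 fell by 1.31, and 3 genes of mitochondrial proteins fell. The tRNA synthetase SARS2 fell by 1.58, the chaperone TRAP1 by 1.04 and the nuclease ENDOG by 1.01. GFUS, which makes GDP-fucose, fell by 1.31 (adjusted p = 0.000433). All 10 kept their calls without any 1 array, and the replicate block called 5736 genes. The test takes the 24 h and 48 h arrays of a replicate number as independent. The residuals of Nnm arrays of the same number correlated across the times at 0.484 to 0.696, and replicate 2 changed less at both. Neither fit models that smaller change, so the evidence rests on 3 replicates and these counts and p can overstate it.

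No single gene passed the test of whether the Nnm change differed between the 2 times (0 of 10907, limma), and 698 had an unadjusted p under 0.05. The smallest p belonged to the deadenylase family gene NOCT (difference 1.01, SE 0.13, adjusted p = 0.122), INHBA (1.98, adjusted p = 0.177), CLCN4 (-1.37, adjusted p = 0.177) and the histone gene H2AC25 (-1.19, adjusted p = 0.213). With the replicate block 2 genes passed, NOCT and COL4A3 (-2.46), each at an adjusted p of 0.0423, COL4A3 being singled out after its values were seen. Only in control 24 h for NOCT and control 48 h for COL4A3 was the group mean above a log2 of 4, so both differences and their SEs rest on values close to background. Without Nnm 24 h replicate 2 the count was 17. As sets, 14 lists differed between the times by camera at the preset correlation, 0 with an estimated correlation and 0 by fry. The cell cycle list had the smallest p, with a median difference of 0.69 and 25 of 25 members positive (camera adjusted p = 5.21e-17, and adjusted p = 0.407 with an estimated correlation).

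In control cells, 14 genes differed between 48 h and 24 h (limma), 9 higher and 5 lower, with no overlap of the 3 and 3 values in 26.3% of genes, where chance gives 10%. The comparison asks which genes change with time in culture. INHBA fell by 2.41 (SE 0.21, adjusted p = 0.00234), the cytoskeletal protein DPYSL3 fell by 1.69, the calcium-binding protein S100A2 by 1.29, the sulfate transporter SLC26A2 by 1.07 (SE 0.10) and NOCT by 0.96 (SE 0.09). The GTPase RAB17 rose by 1.85, the phospholipase PLA1A by 1.68, TFCP2L1 by 1.62 (SE 0.21, or 0.93 with the mean of its probe sets) and the secreted peroxidase GPX3 of the proximal tubule by 1.22. H2AC25 (1.14), the proteoglycan GPC6 (1.01), the syntrophin SNTB1 (1.00), reelin (RELN, 0.98) and SLC35F5 (0.66) also rose. The replicate block gave 924 genes (422 higher and 502 lower), and 1711 had an unadjusted p under 0.05. With arrays centred on their medians 10 genes passed, 5 up and 5 down. The lower means of NOCT (3.53) and RELN (3.36) lay close to background.

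INHBA, SLC26A2 and NOCT kept their calls without any 1 array, and the other 11 each lost theirs without 4 to 10 arrays, at adjusted p of up to 0.265. With the mean of their probe sets RAB17, TFCP2L1, GPC6, RELN, SLC35F5, DPYSL3 and S100A2 did not pass, at adjusted p of 0.0508 to 0.0641. Over the single arrays left out, the count was 8 without Nnm 24 h replicate 1, 4 without Nnm 24 h replicate 3, Nnm 48 h replicate 1 or 3, and control 24 h or 48 h replicate 1. It was 6 without control 24 h replicate 2, 3 without control 24 h replicate 3 or control 48 h replicate 2, and 27 without Nnm 24 h replicate 2.

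In the cell cycle list 0 of 25 genes passed over all genes for control 48 h against control 24 h, and 22 fell adjusted over the list alone, at a median of -0.64 (camera adjusted p = 4.86e-14, and adjusted p = 0.351 with an estimated correlation). In DNA replication 0 of 23 passed and 7 fell adjusted over the list alone, at a median of -0.37 (camera adjusted p = 5.75e-08, and adjusted p = 0.351 with an estimated correlation). The TGF-beta list, with INHBA, lay at -0.34 (camera adjusted p = 0.0013, and adjusted p = 0.351 with an estimated correlation), and 3 of 17 fell adjusted over the list alone. DNA repair lay at -0.24 (camera adjusted p = 0.0219, and adjusted p = 0.635 with an estimated correlation), and 3 of 19 fell adjusted over the list alone. Proximal tubule markers were higher at a median of 0.71 (camera adjusted p = 0.00622, and adjusted p = 0.367 with an estimated correlation), with 0 of 5 past the threshold adjusted over the list alone. Without a filter on low values that median was 0.0039 (adjusted p = 0.0604), and without control 24 h replicate 3 it was 0.46. Distal nephron markers lay at 0.45 (camera adjusted p = 0.0352, and adjusted p = 0.351 with an estimated correlation), where 1 of 5, TFCP2L1, rose (1 adjusted over the list alone), and at 0.0060 without a filter (adjusted p = 0.11) and 0.27 with the mean of probe sets (adjusted p = 0.0499). ATF4 targets lay at 0.28 (camera adjusted p = 0.00986, and adjusted p = 0.672 with an estimated correlation), with 0 of 24 adjusted over the list alone. Cholesterol synthesis lay at 0.19 (camera adjusted p = 0.0452, and adjusted p = 0.672 with an estimated correlation), or 0.29 without control 48 h replicate 2. Metallothioneins lay at -0.26 (camera adjusted p = 0.0452, and adjusted p = 0.672 with an estimated correlation) and ribosome biogenesis at -0.20 (camera adjusted p = 0.0452, and adjusted p = 0.672 with an estimated correlation). In these 3 lists 0 members passed adjusted over the list alone. With the replicate block metallothioneins (adjusted p = 0.117) and ribosome biogenesis (adjusted p = 0.0834) were not called.

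Several control lists lost their calls when single arrays were left out. Some of these were Nnm arrays, which enter this comparison through the pooled spread alone. Without control 24 h replicate 2 the count of lists was 6 in place of 10, and DNA repair (adjusted p = 0.065), ATF4 targets, cholesterol synthesis and metallothioneins were not called. ATF4 targets were also not called without control 48 h replicate 1 (adjusted p up to 0.361). Cholesterol synthesis was also not called without Nnm 48 h replicate 2, control 24 h replicate 1 or control 48 h replicate 3 (up to 0.261). Distal nephron markers were not called without Nnm 24 h replicate 2, control 24 h replicate 1 or control 48 h replicate 3 (up to 0.0977). Metallothioneins were not called without 7 arrays (Nnm 24 h replicates 2 and 3, Nnm 48 h replicate 2, control 24 h replicates 1 and 2, control 48 h replicates 2 and 3, up to 0.185). Ribosome biogenesis was not called without 7 (Nnm 24 h replicates 2 and 3, Nnm 48 h replicates 2 and 3, control 24 h replicate 3, control 48 h replicates 2 and 3, up to 0.611). The 22 other lists tested were not called by camera in this comparison. Fry called 7 lists: the cell cycle, DNA replication, TGF-beta targets, distal nephron markers, PPAR and fatty acid oxidation, xenobiotic metabolism and ribosomal proteins. Of the lists that camera called it left out ribosome biogenesis, DNA repair (fry adjusted p = 0.141), proximal tubule markers (0.114), metallothioneins (0.347), cholesterol synthesis (0.499) and ATF4 targets (0.574).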

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

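No test in this part was chosen after its own result was seen, though the pattern weighed was chosen because the difference between the times had been seen.

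The change that Nnm made in cell cycle genes differed between the times (camera adjusted p = 5.21e-17, and adjusted p = 0.407 with an estimated correlation), with a median difference of 0.69 and 25 of 25 members positive. For this difference 0 members passed over all genes and 9 passed adjusted over the list alone. DNA replication (camera adjusted p = 2.44e-06, median difference 0.40) and DNA repair (0.00128, 0.29) moved the same way, as did TGF-beta targets (0.0123, 0.18) and ribosome biogenesis (0.0123, 0.20). The Nnm change was lower at 48 h than at 24 h in lysosome genes (9.49e-05, -0.28), ATF4 targets (0.000644, -0.43) and metallothioneins (0.00374, -0.29). It was also lower in PPAR and fatty acid oxidation genes (0.00569, -0.29), NRF2 and glutathione genes (0.0123, -0.24) and the unfolded protein response (0.0123, -0.12). The same held for hypoxia and glycolysis genes (0.018, -0.11), fatty acid synthesis (0.0296, -0.17) and oxidative phosphorylation (0.0296, -0.10). Such a difference can also come from control cells, where ATF4 targets (median 0.28) and PPAR and fatty acid oxidation genes (0.17) were higher at 48 h than at 24 h. As 0 genes passed this test over all genes, no list held a called member. None of the 14 was called with an estimated correlation (adjusted p = 0.299 to 0.647 with an estimated correlation) or by fry, and fatty acid synthesis was not called with the replicate block (adjusted p = 0.0558). Over the settings that leave out no single array, the median differences that moved by more than 1.5 times and kept their calls were those of TGF-beta targets (0.37), PPAR and fatty acid oxidation (-0.18) and hypoxia and glycolysis (-0.034) with the mean of probe sets, and of TGF-beta targets (0.44) and the unfolded protein response (-0.22) with array weights, and of the latter (-0.20) without both Nnm replicate 2 arrays.

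With 1 array left out the median differences ran from 0.17 to 0.35 for DNA repair, 0.24 to 0.56 for DNA replication, 0.096 to 0.40 for TGF-beta targets, 0.098 to 0.30 for ribosome biogenesis, -0.46 to -0.18 for lysosome genes and -0.62 to -0.20 for ATF4 targets. For NRF2 and glutathione genes they ran from -0.47 to -0.13, for metallothioneins from -0.37 to -0.17, for the unfolded protein response from -0.24 to -0.046, for hypoxia and glycolysis from -0.27 to -0.045 and for oxidative phosphorylation from -0.20 to -0.0085. Single arrays ended 9 of these calls. ATF4 targets were not called without control 48 h replicate 1 (adjusted p = 0.0632), and metallothioneins not without Nnm 48 h replicate 1 (0.125). The unfolded protein response was not called without Nnm 24 h replicate 3 or Nnm 48 h replicate 1 (up to 0.168). The same held for hypoxia and glycolysis without Nnm 48 h replicate 2 or control 48 h replicate 3 (up to 0.176) and ribosome biogenesis without Nnm 48 h replicate 2 or control 24 h replicate 3 (up to 0.27). NRF2 and glutathione genes were not called without Nnm 24 h replicate 3, Nnm 48 h replicate 2 or control 48 h replicate 3 (up to 0.156), and TGF-beta targets without Nnm 24 h replicate 2, Nnm 48 h replicate 1 or control 24 h replicate 1 (up to 0.112). Fatty acid synthesis was not called without Nnm 24 h replicate 2, Nnm 48 h replicate 1, control 24 h replicate 2 or control 48 h replicate 3 (up to 0.244). Oxidative phosphorylation was not called without Nnm 24 h replicate 2, Nnm 48 h replicates 1 or 3, control 24 h replicate 3 or control 48 h replicate 3 (up to 0.691).

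Behind the cell cycle result, the 25 genes were lower at 48 h than at 24 h in control cells (median -0.64, 25 of 25 lower), while in Nnm-treated cells the median was 0.08 (5 of 25 lower). The mean of the list on an array was 11.06 ± 0.18 in control 24 h, 10.85 ± 0.16 in Nnm 24 h, 10.45 ± 0.14 in control 48 h and 10.93 ± 0.30 in Nnm 48 h (SD, n = 3). By replicate number 1, 2 and 3 it went from 10.94 to 10.34, 10.96 to 10.41 and 11.27 to 10.61 in control cells. In Nnm-treated cells it went from 10.67 to 10.8, from 11 to 10.72 and from 10.86 to 11.27, so replicate 2 was lower at 48 h as well. One array as the cause is argued against, since without any 1 array the median difference was 0.51 to 0.79, at the lowest 0.735 of its value with all arrays. A trend with expression level is argued against too, as the highest median of 10000 random lists of like expression was 0.222. What else underlies it was not tested and stays open.

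Probe sets with no single gene name, which the comparisons of genes leave out, also carried a signal: 257 of 2846 changed at 24 h (117 up and 140 down) and 170 at 48 h (93 up and 77 down) against control arrays of the same time. These are 9.03% and 5.97% of those tested, against 19.4% and 13.8% of the named genes.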

How the results depend on the processing

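Leaving out both Nnm replicate 2 arrays was chosen after the data were seen, unlike the other alternatives. As these Nnm arrays changed least, larger changes and more calls without them follow in part from that choice. Of the 198 results of named genes past the threshold, 198 kept their sign in every setting and 52 stayed past the threshold in every one, with a median of 78.3% of settings. The counts under trend and robust settings, quantile normalisation, median centring and the stricter filter stayed within 1.5 times the main ones. Where a cause is not named below, the cause was not tested.

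Without a filter on low values, which tests more genes, the counts were 1272 at 24 h, 879 at 48 h, 1 for the difference between times (NOCT) and 6 for the control groups, with 11 lists at 24 h. With the mean of a gene's probe sets they were 1 (INHBA) for the difference and 8 for the controls. Array weights, which discount arrays that stand apart, gave 4864, 3468, 37 and 92 genes.

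With the replicate block, which removes the spread shared by arrays of one number, the counts were 4237 at 24 h, 3515 at 48 h, 2 for the difference and 924 for the controls, and with a block within each time 3328 and 2513. The block over all 12 arrays ended 0 calls of named genes and added 48, changed no other call of a list than those printed beside their results, and reversed none. The block within each time ended 4 calls of named genes, IFIT2 (adjusted p = 0.0573), SYNPO (0.0508) and SLC11A2 (0.0645) at 24 h and GATM at 48 h (0.0529), and added 28. With the groups compared alone, which leaves fewer arrays for the spread, the counts were 837, 514 and, for the controls, 4.

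Without both Nnm replicate 2 arrays they were 3703 (1970 up and 1733 down) at 24 h, 3156 (1792 and 1364) at 48 h, 36 for the difference and 63 for the controls, with 10 lists at 24 h. Of the 2116 and 1504 genes, 1990 and 1456 were called again. With an estimated correlation camera called 0 lists at 24 h, 0 at 48 h and 0 for the controls.

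With 1 array left out (2 left in its group, 3 in the others), the counts ran from 404 to 3248 at 24 h, 267 to 2403 at 48 h, 0 to 17 for the difference, 3179 to 4596 for the mean of both times and 3 to 27 for the controls. Lists ran from 5 to 11 at 24 h, 9 to 13 at 48 h and 6 to 12 for the controls, and r across genes from 0.724 (without Nnm 48 h replicate 1) to 0.798.

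Some list calls ended under other settings. Glucocorticoid targets were not called at 24 h with array weights (adjusted p = 0.0863) or without both Nnm replicate 2 arrays (0.0756), and not at 48 h under the stricter filter (0.0747). Metallothioneins at 24 h ended with median centring (0.0527), DNA replication at 48 h under the stricter filter (0.0514), the mean of probe sets (0.0571) and without both replicate 2 arrays (0.0584), and histone genes at 48 h without a filter (0.144). Without a filter the control lists of proximal tubule (0.0604) and distal nephron markers (0.11) also ended. So did the differences between times of ATF4 targets (0.0986), PPAR and fatty acid oxidation (0.0977), NRF2 and glutathione genes (0.192), the unfolded protein response (0.185), fatty acid synthesis (0.185), hypoxia and glycolysis (0.16) and oxidative phosphorylation (0.192). With array weights the differences of fatty acid synthesis (0.14), hypoxia and glycolysis (0.0744), oxidative phosphorylation (0.123) and ribosome biogenesis (0.0599) ended, and so did ribosome biogenesis in the controls (0.0598). Without both replicate 2 arrays the differences of fatty acid synthesis, oxidative phosphorylation and ribosome biogenesis ended (0.0627 each), as did metallothioneins (0.073) and ribosome biogenesis (0.068) in the controls. These last 2 also ended under the stricter filter (0.0615 each). With the groups compared alone, distal nephron markers (0.057) and ribosome biogenesis (0.0732) ended in the controls, and with a block within each time metallothioneins at 24 h (0.0701) and the difference of fatty acid synthesis (0.0677).

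Other settings also called lists that the planned test did not. Without a filter these were fatty acid synthesis (0.0248), the cell cycle (0.00703), DNA replication (0.0298), interferon (0.0298) and TGF-beta targets (0.0124) at 24 h, and NRF2 and glutathione (0.0178) and immediate early genes (0.015) at 48 h. Heat shock (0.00466) and ribosomal proteins (0.00414) in the controls and the difference of NF-kB genes (0.00395) were others. Array weights added NRF2 and glutathione (0.0259), PPAR and fatty acid oxidation (0.0397) and immediate early genes (0.00816) at 48 h, PPAR and fatty acid oxidation in the controls (0.0418) and the difference of iron handling (0.0318). Without both replicate 2 arrays the last 2 were called too (0.0462 and 0.0289), besides the 8 lists of 24 h and 48 h named in the report. The groups compared alone added histone genes at 24 h (0.0151), a block within each time the cell cycle at 24 h, and the mean of probe sets ribosomal proteins in the controls (0.0434) and the difference of iron handling (0.041). Xenobiotic metabolism in the controls passed with quantile normalisation (0.0461) and median centring (0.0455). Of lists that kept their calls, the medians without a filter, which adds members, were 0.42 (NRF2 and glutathione) and 0.35 (glucocorticoid) at 24 h and 0.32 (interferon) and 0.27 (glucocorticoid) at 48 h.

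With the mean of their probe sets 32 results of named genes did not pass. The changes of CYCS and PGK1 at both times and of THBS1 at 24 h grew by more than 1.5 times. Those that shrank by as much were NRG1 (-0.92), ZFHX4-AS1 (-1.67), TFCP2L1 (1.07), OCLN (0.33), PPM1D (0.31), TNFRSF10A (-0.32), SLC11A2 (0.25) and WDR12 (-0.35) at 24 h. At 48 h they were those of NEGR1 (1.94), ABCC3 (0.42), MCM10 (0.70), ICAM1 (-0.63), SCNN1A (0.32) and CDH6 (0.52), and between the controls TFCP2L1 (0.93). Signal close to background limits every change with a group mean under a log2 of 4 on either side, such as those of PCK1 at both times (3.08 to 3.89 at 24 h), OAS1 at 24 h, CYP2J2 at 48 h and NR2F1-AS1.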

Other observations

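The gene families below were chosen after the data were seen, and so were the tests of a swap, of a replicate 2 batch and of gene length and expression, the slopes of replicate 2, and the fits of all splits that part the 6 pairs and of those that exchange whole replicate numbers.

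Of 76 mitochondrial ribosomal protein genes (MRPL and MRPS) 31 fell at 24 h and 12 at 48 h, with medians of -0.37 and -0.24 (camera adjusted p = 5.56e-12 and 7.13e-09 over 14 families, and adjusted p = 0.207 and 0.209 with an estimated correlation). Of 21 import genes (TIMM and TOMM) 10 and 5 fell, with medians of -0.49 and -0.45 (camera adjusted p = 6.18e-06 and 7.56e-05, and adjusted p = 0.106 and 0.208 with an estimated correlation), and of 41 complex I genes (NDUF) 8 and 10 fell. Of 29 aminoacyl-tRNA synthetases 5 fell at each time (medians -0.33 and -0.31, camera adjusted p = 1.6e-05 and 9.3e-06, and adjusted p = 0.0903 and 0.0772 with an estimated correlation). Of 46 proteasome genes 7 fell and 2 rose at 24 h and 4 fell (8 with arrays centred on their medians) and 2 rose at 48 h, and of 7 chaperonin (CCT) genes 5 fell at 24 h and 1 at 48 h. The 56 cytosolic ribosomal protein genes (RPL and RPS) had medians of 0.04 at both times, with 0 called at 24 h and 1 higher at 48 h.

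Zinc finger (ZNF) genes mostly encode transcription repressors. Of 350 tested, 68 rose and 3 fell at 24 h and 92 rose and 1 fell at 48 h, with medians of 0.24 and 0.27 (camera adjusted p = 1.23e-05 and 7.13e-09, and adjusted p = 0.0903 and 0.0256 with an estimated correlation). In control cells between 24 h and 48 h their median was 0.04 and 0 were called. A trend with gene length or expression level is argued against, since the highest median of 10000 lists matched on both was 0.0998 at 24 h and 0.105 at 48 h. Cross-hybridising probe sets of related genes are argued against as the whole cause, since the 250 ZNF genes on probe sets without a suffix for shared sequence had medians of 0.99 and 0.983 of that of all. GC content and the authors' background subtraction by probe sequence stay open, and so does an effect of Nnm on these genes, each untested.

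The Nnm arrays of replicate 2 changed less than the other Nnm arrays, at 0.482 and 0.504 (24 h) and 0.383 and 0.394 (48 h) of the slope of replicate 3 or 1 against the same reference, which held no array of the numbers compared. Of the genes that moved by more than 1 log2 unit in the mean of replicates 1 and 3 at the other time, 93.6% and 85.2% had the same sign in replicate 2. A swap with a control array is argued against, since no control array lay further than 0.0534 of the Nnm change toward the Nnm arrays (-0.0979 to 0.0534). A batch that shifts all replicate 2 arrays along the Nnm change is argued against by the control arrays of replicate 2. They lay at 0.0534 and 0.0463 of that change, though they share the ACTB difference. A batch that shrank the Nnm change alone would leave the control arrays in place, so this test cannot decide on it. Mixing with control RNA acts on the signal before the logarithm, so it would leave rising genes less reduced than falling ones. It cannot be told apart from a weaker response here, since the slope of rising minus falling genes was 0.03 and 0.089 on replicate 2, within the range of -0.15 to 0.189 (SD 0.143) on the others. The exposure of these cultures was not tested, and the cause stays open.

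Other splits of the arrays were fitted in the same way. The 6 arrays of a comparison make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 2116 genes at 24 h, 1504 at 48 h and 14 between the control groups, and the highest of the others 0 in each, so 1 split reached the real count. As the replicate numbers pair the arrays, 4 of the 10 splits part all 3 pairs, and of these the highest other was also 0. For lists the real counts were 6, 10 and 10 and the highest others 13, 10 and 8, with 5, 2 and 1 of the 10 splits reaching the real count. The numbers of lists at 24 h and 48 h thus do not stand apart from those of other splits. For the mean of both times 1 of 100 drawn splits reached 4067 genes, with 870 as the highest other, from a split that parts fewer pairs. Of the 32 splits that part all 6 pairs, each fitted, 1 reached 4067, the real one, and the highest other was 0. The numbers also pair the arrays across the times, and exchanging whole numbers makes 4 splits, too few for a share under 0.05, with 4067 for the real one and 0 as the highest other (1 of 4 reached the real count). For the difference between times the real count was 0, which all 100 drawn splits reach by construction, so these splits say nothing about chance there. The highest other was 4067, from the split that exchanges the labels at one time and so measures the Nnm change itself, a structure of the samples.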
